A study of Solanum lycopersicum x Solanum pimpinellifolium with 16 samples.

How the data were processed

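Root RNA of grafted tomato was measured on 16 single-colour arrays. The rootstocks were the near-isogenic lines E9 and L5, from a cross of S. lycopersicum var. cerasiforme with S. pimpinellifolium, and every rootstock carried a Boludo scion. Each line was grown under control irrigation and under combined low phosphorus and drought, which made 4 groups of 4 biological replicates. The labels conflict on this point, since the extraction text gives 3 replicates per treatment while the titles and the design text give 4; the 16 arrays were taken as 4 per group.

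Per the labels and the file headers, total RNA was labelled with Cy3, hybridised to a custom Agilent array of 60-mer probes designed on build 2.4 of the Heinz 1706 genome, and quantified with Agilent Feature Extraction 12.0.2.2. Each array held 180880 spots, of which 176026 were not controls, and these covered 34619 transcripts. Of the transcripts, 28932 had 5 probes. The deposited scan files held spot intensity on the scanner's linear scale: the raw median intensity of each spot and of its local background, and a processed signal with background subtracted within the array. They also held other columns, the deposited flags of 0 or 1 for spots well above background, saturated spots and outlier spots. The authors' value table was in log2 units after Robust Multichip Averaging, with 1 value per transcript. The version and the settings of that averaging were not given in the sources used here.

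Values were computed from the scan files with R 4.3.3, limma 3.58.1 and data.table (version 1.17.8). Since the labels name Robust Multichip Averaging, the raw median intensity was background corrected with normexp (saddle method, foreground alone, no offset), arrays were quantile normalised, log2 was taken, the spots of a probe were averaged and the probes of a transcript were summarised by median polish over the 16 arrays. The plan named the mean spot intensity. The files used here held no such column, so the median spot intensity took its place. Control spots and outlier spots were left out after the background step. Saturated spots were kept. A transcript was tested when at least 50% of its probes were well above background on all 4 arrays of at least 1 group. That gave 22696 transcripts, of which 4 lacked a value on some array, and the other 22692 were tested.

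Comparisons used limma with 1 mean per group and all 16 arrays in a single model, two-sided moderated tests, and Benjamini-Hochberg adjustment over the 22692 transcripts. A transcript was called at an adjusted p under 0.05 with no minimum fold. The contrasts were stress against control in each line and averaged over both lines, L5 against E9 in each condition and averaged over both conditions, and the line by stress interaction, which is the stress effect in L5 minus that in E9. The SE printed with a log2 difference is the moderated standard error of limma. Each slide held 1 array of every group with the same replicate number, so a replicate block was also a slide block. All 4 arrays of a slide were scanned together, so a separate block for scan date was not run. Residuals of arrays with the same replicate number correlated by 0.219 to 0.425 between E9 control and L5 control, and by -0.375 to 0.362 over the other pairs of groups. The main model did not pair arrays by replicate number. The replicate block and the counts of signs by slide did group arrays by it. Between E9 control and L5 control the own number was the best match for 1 of 4 E9 control arrays, so pairs were not established. Between E9 stress and L5 control it was the best match for 3 of 4 E9 stress arrays, with correlations of 0.0933 to 0.269.

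Called line differences were counted by chromosome, read from the digits after Solyc in the identifier, with a one-sided Fisher's exact test for excess and adjustment over the chromosomes. The planned scan looked for windows of 50 consecutive tested transcripts with over 30% called. A lower share of 15% was used to mark a segment after the data were seen. Probe agreement was the share of called transcripts with at least 3 probes whose probes all had the transcript's sign. A departing probe was one more than 1 log2 unit from its transcript's line difference. Since median polish lets a single probe hardly move a transcript, values were also computed as the mean of at least 3 probes, with and without the probe that differed most in the transcript's direction.

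Of 33 gene lists written before the data were examined, 27 were defined by words in gene descriptions. The files give identifiers without descriptions, so those 27 lists were void, among them all markers of other cell types (dividing cells, endodermis and exodermis, xylem, green tissue). The other 6 lists held loci given by identifier, and the 3 with at least 5 tested members were tested with limma's camera (preset correlation 0.01), with camera under an estimated correlation and with fry, each adjusted over the 3 lists. The 6 list means were also compared between lines by an exact two-sided permutation of the line labels within each condition, with 4900 assignments and adjustment over the 6 lists. The membership of these lists came from general knowledge of tomato loci and was not checked against an annotation.

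The rule for named transcripts, written before the data were examined, took 10 rises and 10 falls called in both lines alone for stress, 8 and 8 called in both conditions alone for the line difference, all interaction calls, up to 4 members of each list, and the phosphate transporter and abscisic acid synthesis members. Its condition that a stress transcript have a description could not be applied. Since the files do not pair identifiers with names, at most 2 unlisted identifiers that rose and 2 that fell are printed per comparison.

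The alternatives, apart from those named here, were chosen before the data were examined: 75th percentile scaling of the processed signal, the authors' value table, normexp with local background and an offset of 50, no background correction, the mean of probes, no filter and a strict filter on all arrays, a replicate block, variance trend with robust estimation, array weights, only the groups of a contrast, a 2-fold minimum, and each array left out. Leaving out arrays for the lists and the chromosome share, leaving out departing probes, probe agreement under a block or a strict filter, and dropping members of the phosphate list were chosen after the data were seen. The procedure was tested on simulated data with the spread of these arrays: at a true change of 0.5, 1 and 2 log2 units it recovered 74.6%, 98.5% and 100% of 67, 67 and 66 changed transcripts for stress averaged over both lines, and 19.4%, 70.1% and 95.5% for the interaction. In each simulation no other transcripts were changed, the noise was independent, and a transcript had the same spread in every group. In the data 47.9% of the tested transcripts were called for stress averaged over both lines, so the recovered shares need not hold there. The number of arrays limits the precision.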

Results

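Transcript levels were measured in roots of the tomato rootstock lines E9 and L5 after 29 days of growth in perlite at 22 °C. Control plants received Hoagland's solution with 1 mM H3PO4 daily to pot capacity. Stressed plants received no added phosphate for 19 days, and then 10 µM H3PO4 with irrigation to 70% of pot capacity for 10 days. Each of the 4 combinations of line and treatment had 4 arrays. Median spot intensity ran from 231 in L5 stress replicate 4 to 597 in E9 stress replicate 1, and the share of spots well above background ran from 57.9% in E9 control replicate 4 to 76.8% in L5 stress replicate 2. Replicates within a group correlated at 0.977 to 0.995 across transcripts, which are not independent replicates.

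The first principal component held 63.4% of the variance and parted all 8 stressed from all 8 control arrays. The second held 7.93%. On it the E9 stress arrays lay between -27.8 and -0.12 and the L5 stress arrays between 3.60 and 38.8. L5 stress replicate 2 lay farthest out, and E9 stress replicate 3, at -0.12, lay apart from the rest of its group, at -16.7 or lower. The median SD between replicates was 0.13 in E9 control, 0.12 in E9 stress, 0.12 in L5 control and 0.16 in L5 stress (log2, n = 4 each).

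**Figure D1:**
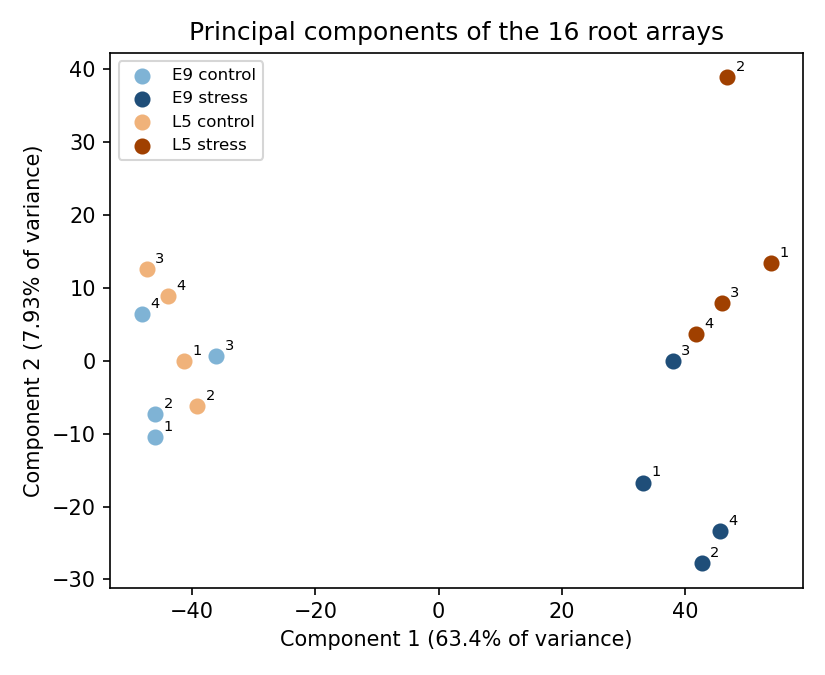
Each point is 1 array, coloured by group and numbered by replicate; the axes are the first 2 principal components of log2 expression, in component units. Control arrays sit between -48.1 and -36.1 on component 1 and stressed arrays between 33.2 and 54.0.

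What combined low phosphorus and drought did to root transcripts was the question of the comparison averaged over both lines. Of the 6 tested phosphate transporters, which carry inorganic phosphate across membranes, 4 rose and the other 2 did not pass the test. The largest rises in that list were in Solyc09g066410, higher by 3.50 ± 0.12 (log2, SE, 8 arrays per side), and Solyc09g073010, higher by 2.96 ± 0.12. Of the 13 tested members of the abscisic acid list, which covers the hormone of the drought response, 9 rose and 1 fell, with the largest rise in Solyc03g096670 at 2.60 ± 0.32. All 3 members of the dehydrin, LEA and ASR list, proteins that accumulate in drying tissue, rose, by 1.12 to 4.30. Tested in E9 alone and in L5 alone, 2 of the 3 were called. The rise of Solyc10g078770, 1.54, was 1.09 without E9 stress replicate 4. In the iron uptake and storage list 4 of 5 tested members fell and 1 rose.

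The phosphate list moved up against all other transcripts (camera adjusted p = 1.69e-05, and 0.0052 with an estimated correlation). The abscisic acid list moved up with an adjusted p of 0.000348, which became an adjusted p of 0.121 with an estimated correlation. The iron list moved down with an adjusted p of 0.0177, which also became an adjusted p of 0.121 with an estimated correlation. Adjusted over the list alone, 5 phosphate, 10 abscisic acid and 5 iron members passed. The largest fall in the iron list was in Solyc02g069200, at -1.99 ± 0.15, followed by Solyc01g100490 at -1.95 ± 0.14, and the rise was in Solyc06g051550, at 1.07 ± 0.21. Of the abscisic acid synthesis loci, Solyc07g056570 was higher by 1.65 ± 0.38 and Solyc08g016720 by 1.06 ± 0.19. The latter had a probe above background on 7 of 16 arrays, so its size depends on the background step; it was 0.71 with no background correction. The fall in Solyc08g005610, at -0.58 ± 0.20, lost its call in 8 of 26 alternatives, and the rise in Solyc05g052980, at 0.65 ± 0.26 with an adjusted p of 0.0494, in 15 of 26. Of 4 tested members of the strigolactone and symbiosis list 2 rose, Solyc09g065750 by 2.35 ± 0.20 and Solyc08g066650 by 0.61 ± 0.15, and both members of the osmolyte list rose, Solyc06g019170 by 1.00 ± 0.09 and Solyc08g043170 by 0.17 ± 0.05.

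Across all 22692 tested transcripts 10863 were called for stress, 4638 higher and 6225 lower (10960 with a replicate block). The largest rises were in Solyc09g089510 at 7.71 ± 0.34 and Solyc09g089490 at 7.30 ± 0.36, which lie close together on chromosome 9. Solyc09g089510 was above background on none of the 8 control arrays and Solyc09g089490 on 1, so their sizes depend on the background step, and with no background correction they were 6.73 and 6.27. The largest falls were in Solyc11g069760 at -5.61 ± 0.13 and Solyc04g025750 at -5.51 ± 0.18. A change of at least 2-fold was seen in 983 higher and 578 lower transcripts. Within each slide, 10219 of the 10863 called transcripts, or 94.1%, had the same sign on all 4 slides; these are the arrays that made the calls. Detection above background on all 8 stressed arrays and on none of the 8 control arrays was found in 10 transcripts, and the opposite in 0.

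How far the response was shared was asked by testing each line alone. The phosphate list had 4 members that rose in E9 and 5 that rose in L5, and all 5 tested iron members passed in both lines with the same directions. The abscisic acid list had 7 members that rose in E9 and 5 in L5; whether these differ is the subject of the interaction. In E9 5973 transcripts were called, 2988 higher and 2985 lower. In L5 8914 were called, 3589 higher and 5325 lower (4234 and 4604 with 75th percentile scaling). In both lines 2384 were higher, against 473 if the calls were independent, and 2502 were lower, against 700; 1 was called in opposite directions. The effects correlated at 0.904 across transcripts, with no array in common between the lines.

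**Figure D2:**
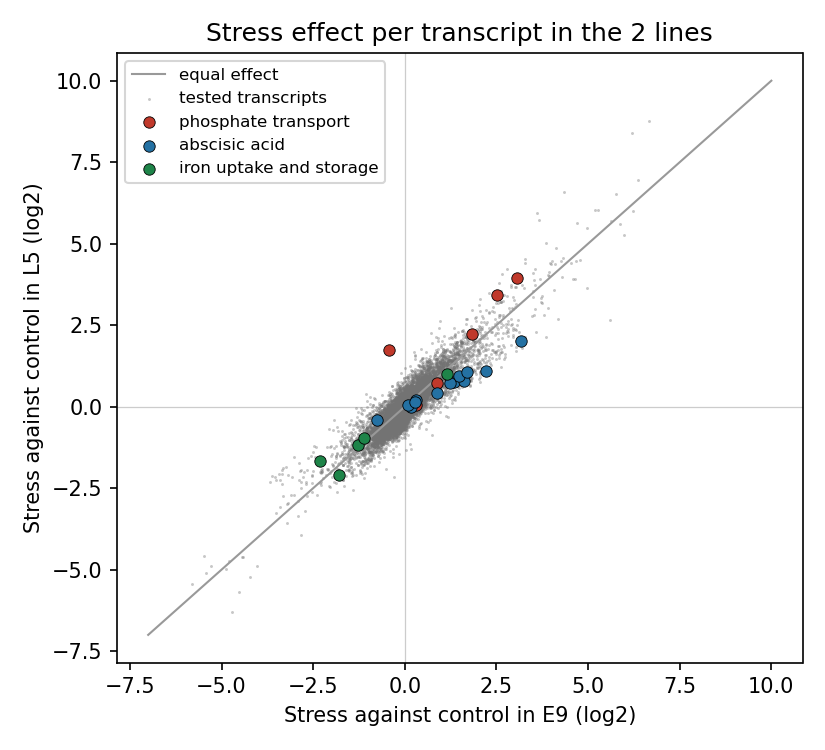
Each point is 1 tested transcript, with the stress effect in E9 on the horizontal and in L5 on the vertical axis (log2); coloured points are tested members of 3 gene lists, and the line marks equal effects. The slope of L5 on E9 by total least squares was 1.07.

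The larger number called in L5 did not come with more large changes throughout: 322 transcripts were called at 4-fold or more in L5 and 356 in E9, while 1751 and 1466 were called at 2-fold or more. Without L5 stress replicate 2, which had the most outlier spots at 0.867% against 0.19% or less in its group, the counts were 8006 in L5 and 6492 in E9.

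Which transcripts differ between the near-isogenic lines was asked by L5 against E9, averaged over both conditions. The differences concentrated on chromosome 9, where 111 of 1656 tested transcripts, or 6.70%, were called, against 1.47% elsewhere. A stretch from Solyc09g011140 to Solyc09g075360 held 102 of them among 808 tested, 48 higher and 54 lower in L5. Among the strongest falls was Solyc09g056200, measured by 2 probes, at -4.85 ± 0.12 (log2, SE, 8 arrays per side), which was above background on all 8 E9 arrays and on no L5 array. Solyc09g018670 in the same stretch was at -4.59 ± 0.08. Of the transcripts called in both conditions alone, the largest rises were in Solyc07g062280 at 2.11 ± 0.29 and Solyc09g075360 at 1.34 ± 0.13. Solyc07g062280 was above background on 1 of 4 E9 control arrays, and was 1.53 with no background correction and 1.31 with local background and an offset.

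In all, 421 transcripts were called, 210 higher and 211 lower in L5 (374 with a replicate block, 647 with array weights, 278 without E9 stress replicate 4), and 25 of them differed at least 2-fold. With 75th percentile scaling the division was 245 higher and 161 lower. The excess on chromosome 9 had an adjusted p of 1.03e-32 by Fisher's exact test, and each other chromosome had an adjusted p of 1. No chromosome had an excess of stress calls (lowest adjusted p = 0.094). No window of 50 transcripts had over 30% called; the highest was 24%, on chromosome 9. The stretch was therefore marked by a 15% share chosen after the data were seen. Outside it 9 of 848 transcripts on chromosome 9 and 310 of 21036 on other chromosomes were called. All 6 differences of at least 4-fold in the stretch were lower in L5. All probes had the transcript's sign in 87.1% of 93 called transcripts of the stretch, against 87.8% of 98 stress calls of matched size. Median polish sets single probes aside, so these shares cannot tell whether base differences under single probes made the calls. A departing probe was held by 13 of the 93 and by 1 of the 98. Departure was measured on the line difference in both sets, so the stress calls were not checked against their stress effect. A probe departed from its transcript in 0.767% of the probes of the stretch and 0.0647% of those on other chromosomes. The levels of Solyc09g056200 and Solyc09g018670 in L5 were near background, and their differences were -3.75 and -3.62 with no background correction, so the order of the strongest falls depends on the background step.

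**Figure D3:**
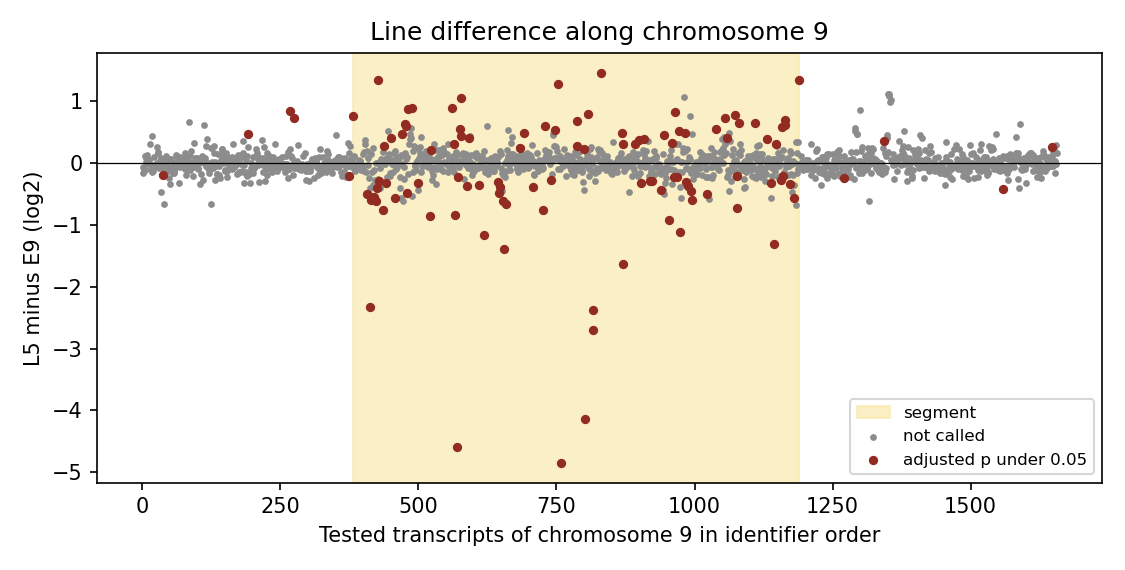
Each point is a tested transcript of chromosome 9 in identifier order, with the L5 minus E9 difference (log2) averaged over both conditions; dark red points are called and the shaded band is the stretch from Solyc09g011140 to Solyc09g075360. The difference of Solyc09g056200 is -4.85.

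Among the lists, 2 phosphate transporters were higher in L5, Solyc09g073010 by 0.64 ± 0.12 (adjusted p = 0.0128) and Solyc09g066410 by 0.54 ± 0.12 (adjusted p = 0.0344), and the list moved up (camera adjusted p = 0.00051, and 0.0183 with an estimated correlation). In control these 2 differences were 0.18 (adjusted p = 0.997) and 0.11 (adjusted p = 1), and in stress 1.10 (adjusted p = 0.00602) and 0.98 (adjusted p = 0.0121). Both loci lie in the chromosome 9 stretch, and without them the list had an adjusted p of 0.123. The abscisic acid list had a camera adjusted p of 0.123 and the iron list 0.618, and limma called 0 members of these or of the dehydrin, strigolactone and osmolyte lists.

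Taken by condition, 125 transcripts differed between the lines in control roots, 73 higher and 52 lower in L5 (108 with a replicate block, 78 with only the groups of the contrast, 212 with array weights), and 288 in stressed roots, 129 higher and 159 lower (255 with a block). With only the groups of the contrast the latter count was 59, 31 higher and 28 lower, so stress no longer had the larger count. With 75th percentile scaling the latter division was 144 higher and 90 lower. Chromosome 9 held 49 of the 125 and 76 of the 288. Of the calls 74 were shared, 41 higher and 33 lower in both, and 0 were opposite. The count in stressed roots moved from 90 without E9 stress replicate 4 to 646 without E9 stress replicate 3, and was 140, 155 and 190 without E9 stress replicates 1 and 2 and L5 stress replicate 2. The count in control roots was 76, 80 and 76 without E9 control replicate 1, E9 control replicate 2 and L5 control replicate 4.

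Whether the stress response itself differed between the lines was asked by the interaction. In 1 transcript the difference passed the test: Solyc09g059630, in the chromosome 9 stretch, rose by 1.26 ± 0.16 in E9 and by 3.03 ± 0.16 in L5 (4 arrays per group), a difference of 1.77 ± 0.23 with an adjusted p of 0.0249 in limma. That call was lost with a replicate block (adjusted p = 0.191), with 75th percentile scaling, and in 12 of the 16 models that left out an array. Without E9 stress replicate 3 the interaction count was 23, 6 higher and 17 lower, and without E9 stress replicate 1 it was 2. The mean of the phosphate list rose more in L5, by 0.66 (log2), and this difference was positive on 4 of 4 slides. Slide counts of the lists, here and below, use the arrays that gave the means, so they add no separate evidence. Of the 6 members 4 had a positive and 2 a negative difference, so the mean does not stand for all of them. Their list mean went from 9.50 ± 0.11 to 10.86 ± 0.23 in E9 and from 9.47 ± 0.07 to 11.49 ± 0.12 in L5 (log2, SD, n = 4).

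The phosphate list had a camera adjusted p of 0.000173 for the interaction, 0.0119 with an estimated correlation, and an exact permutation p of 0.0118 (0.0355 adjusted over 6 lists). No single member passed over all transcripts, and 4 passed adjusted over the list alone. The largest difference was in Solyc03g005530, which was -0.44 in E9 and 1.73 in L5 and had an SD of 1.05 in E9 stress; without it the mean difference was 0.36 and the exact permutation p 0.0894, while camera gave an adjusted p of 0.00601. Without the pair of loci in the chromosome 9 stretch the mean was 0.54 and the exact permutation p 0.011. The 4 members left include Solyc03g005530, whose difference was 2.17, so this mean rests largely on that locus. Leaving out the pair and that locus together was not run. The abscisic acid list had a mean difference of -0.46, negative on 3 of 4 slides, with an adjusted p of 0.0177. Its adjusted p was 0.345 with an estimated correlation, and its exact permutation p was 0.126 (0.252 adjusted). Of its 13 members 12 had a negative difference, and none passed the test. The 2 osmolyte loci had a mean difference of -0.30, negative on 3 of 4 slides, with an exact permutation p of 0.00857 (0.0355 adjusted). Their own differences were -0.48 and -0.11, limma called 0 of them, and 1 passed adjusted over the list alone. In E9 stress the list mean was 13.15 and 13.16 in replicates 2 and 4, against 12.92 and 12.83 in replicates 1 and 3. The exact permutation p was 0.264 for the strigolactone list, 0.278 for the dehydrin list and 0.762 for the iron list, whose camera adjusted p was 0.327.

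**Figure D4:**
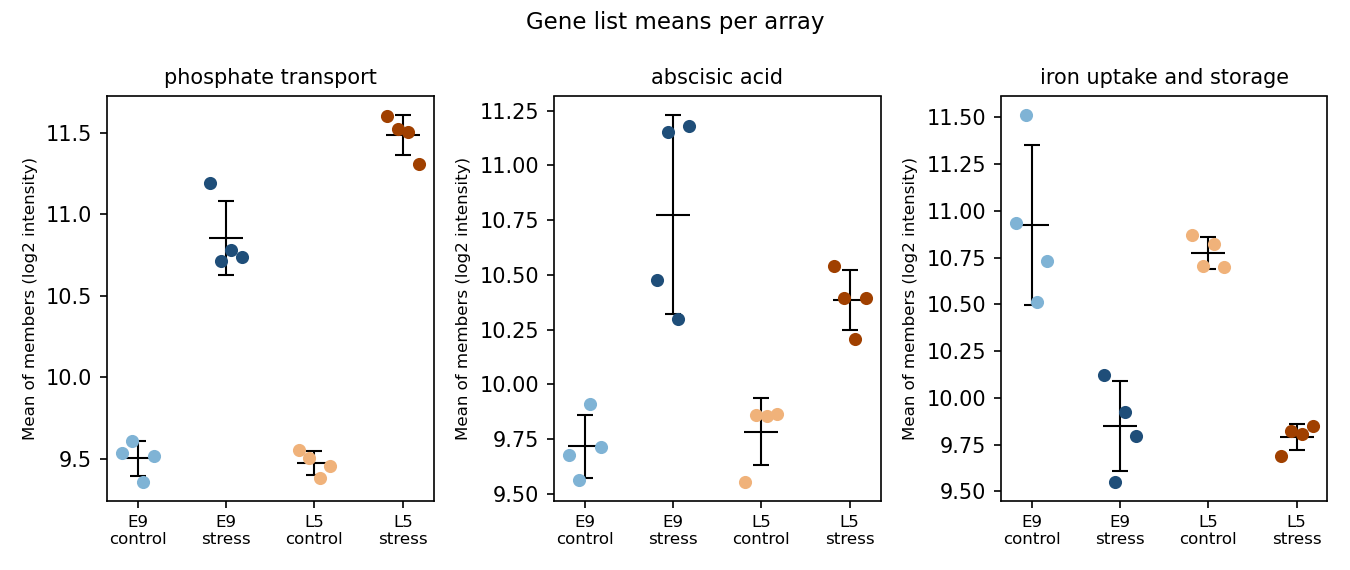
Points are the mean log2 intensity of a list's tested members on each array, and bars are the group mean with its SD (n = 4); the vertical axes do not start at 0. The phosphate mean is 10.86 in E9 stress and 11.49 in L5 stress.

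At an unadjusted p under 0.05 the interaction held 2081 transcripts, where 1135 would pass by chance on average. Transcripts are not independent, and the spread of that count over splits of the arrays was not computed, so the excess was not tested.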

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

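The tests that left out a probe, of the share higher in L5, of differences of at least 4-fold, of single arrays behind the L5 count, of signs and split counts outside the stretch, of splits that part all pairs, and of chromosome 9 and shared calls in control were chosen after the values were seen; the others were planned, although the stretch some of them use was marked after. The planned test of probe signs (87.1% with all probes on the same side) was void, since median polish sets single probes aside. Every count of splits includes the real division of the arrays.

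The excess of line differences on chromosome 9 was weighed against base differences under the probes, which were designed on Heinz 1706. With the probe farthest in the transcript's direction left out of the mean of probes, single probes as the whole cause are argued against by a chromosome 9 share of 28.7% of line calls (adjusted p = 2.07e-22) and, over 100 called transcripts of the stretch, by a median 0.896 of the difference left (quartiles 0.787 and 0.940, with 0.906 for stress calls); 63% stayed called (95% exact interval 52.8 to 72.4, between the bounds of 40% and 70%, with 57.0% for all line calls and 79.6% for stress calls), the 37 lost calls going from a median adjusted p of 0.0281 to 0.126 and a median size of 0.30 ± 0.06 to 0.24 ± 0.07 (log2, SE), and 6 transcripts lost most of their difference, so for these a single probe stays open. Weaker hybridisation of the L5 allele alone needs over 70% lower in L5. For the stretch as a whole it is argued against by 47.1% of 102 that were higher. The interval, 37.1 to 57.2, shuts out under 30% but reaches below the 40% set as the opposite bound. For differences of at least 4-fold, 100% of 6 were lower (interval 54.1 to 100). That interval reaches below 70%, so 6 transcripts are too few to place the share against the bound. Lower expression in L5 gives the same direction, so the direction cannot tell it apart from weaker hybridisation. Base differences that weaken the allele of either line need not favour a direction, so the division of signs cannot test them. Departing probes of the stretch went both ways, 15 lower and 13 higher in L5. Base differences under several probes of a transcript were not tested either. A segment that differs between the lines may account for the rest: 100% of 46 transcripts called in control had the same sign in stressed plants, but 75 of 79 outside the stretch did too, so this shows repeatable differences and does not single out a segment. Of 100 splits of the line labels within each condition 2 called as many transcripts as the real 421, so chance can be excluded at that share; the other, with 594, parted the control arrays of both lines into slides 1 and 2 against slides 3 and 4, and called 0 with a replicate block, where the real count was 374.

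More transcripts were called for stress in L5 than in E9, by 2941. Of 100 splits of the line labels 1, the real split, had a difference as large, but the highest other split came close at 2833. Chance is therefore excluded at that share alone and by a narrow margin. The splits took no account of slides, and with a replicate block 9055 were called in L5 and 6223 in E9. A single array as the whole cause is argued against by the smallest difference with any array left out, 1514, without L5 stress replicate 2. That is well below the full difference, and the splits were not repeated without that array, so chance together with it stays open. With array weights 9144 were called in L5 and 7217 in E9. A larger response in L5 stays open as an untested biological explanation: 1 transcript passed the interaction test, and the slope of 1.07 was not tested.

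Line differences outside the chromosome 9 stretch numbered 319, and 2 of 100 splits had as many, with 581 in the highest other. A difference in the extent of the stress response would need the line difference to follow the stress effect at an r over 0.3 across transcripts; it was 0.16, and 38 of 100 splits were as large, so this cannot be told apart from chance. A second segment would need a window over 30% called off chromosome 9; the highest was 14%, on chromosome 6. Its interval, 5.82 to 26.7, shuts out over 30% but reaches past the lower planned bound of 15% and past the 24% at which the chromosome 9 stretch itself peaked, so a second segment of that density cannot be told apart with 50 transcripts. Other small introgressions that these lines could carry stay open, as untested.

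For stress against control, 1 of 35 splits of the E9 arrays gave as many calls as the real 5973 (highest other 1), 1 of 35 of the L5 arrays as many as 8914 (highest other 6), and 1 of 100 as many as 10863 averaged over both lines (highest other 3), so chance can be excluded for each. For L5 against E9 in stress 1 of 35 gave as many as 288 (highest other 44), and chance can be excluded for that count, which was 59 with only the groups of the contrast. In control 2 of 35 gave as many as 125, so chance was not excluded by this count. The other, with 1129, several times the real count, was slides 1 and 2 against slides 3 and 4. In the stressed arrays of the same slides the highest split by slide gave 0. The division was therefore seen in the control arrays alone, which argues against an effect of the slide common to all its arrays. Its cause was not tested. The count with a replicate block was 108, but that block is shared by all 4 groups and does not model a division of the control arrays alone. Chance as the whole cause is argued against by 49 of the 125 on chromosome 9 (adjusted p = 9.04e-23) and by 74 that were also called in the stressed plants, with 0 opposite. Among the 8 splits that part all 4 pairs of equal replicate number, as the real one does, the highest other gave 0. These 8 splits are too few for a share under 0.05, and the pairs themselves were not established. The remaining splits leave some pairs together. For the interaction 6 of 100 gave as many as the real 1 (highest other 2), and chance was not excluded.

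The stress effect differed between the lines by a test of the difference for Solyc09g059630 (1.77, an adjusted p of 0.0249 that was 0.191 with a replicate block, where chance was not excluded). It also did for the phosphate list mean (0.66, but 0.36 with an exact permutation p of 0.0894 without Solyc03g005530). The abscisic acid list mean (-0.46) passed by camera with the preset correlation alone (adjusted p 0.345 with an estimated correlation, 0.147 with fry, exact permutation p 0.126). The osmolyte list mean (-0.30) passed by permutation alone, with its 2 members at -0.48 and -0.11.

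In 204 groups of 4 arrays 13 had a single array far from the others, where chance gives 10.2. Solyc04g078840 was 11.97 in E9 control replicate 3, against 11.41 to 11.45 in the others. The median spot intensity of E9 stress replicate 1 was 597, against 379 to 394. In E9 stress replicate 4 Solyc02g084850 was 16.00, against 14.74 to 14.93, Solyc10g078770 was 11.53, against 7.87 to 8.04, and the dehydrin list mean was 14.28, against 12.41 to 12.65. The highest value of that array in the authors' value table was also 16.00. Whether saturated spots limited the level of Solyc02g084850, and so its stress rise of 4.30, was not tested. The phosphate list mean of E9 stress replicate 1 was 11.19, against 10.71 to 10.78. Solyc09g059630 was 7.69 in L5 control replicate 3, against 7.97 to 8.02. In L5 control replicate 1 Solyc07g056570 was 7.10, against 8.86 to 8.96, and the abscisic acid list mean was 9.55, against 9.86 in each of the others. In L5 control replicate 2 Solyc02g069200 was 9.68, against 10.10 to 10.17, and Solyc11g018530 was 10.98, against 11.24 to 11.25. L5 stress replicate 2 had 76.8% of spots well above background, against 67.7% to 68.6%, and 0.867% outlier spots, against 0.0795% to 0.19%.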

How the results depend on the processing

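Leaving out arrays for the lists and the chromosome share, leaving out departing probes, probe agreement under a block or a strict filter, and dropping list members were chosen after the data were seen; the other alternatives were planned. Scan date was not run as a block, since it did not differ within a slide, and the slide block was the replicate block. The counts for stress stayed within 1.5 times in every alternative but the 2-fold minimum: averaged over both lines 9029 to 11975, in E9 4821 to 7217, in L5 7477 to 9329, and with an array left out 10096 to 10881, 4951 to 6492 and 7651 to 8924. With a 2-fold minimum, which by its construction passes fewer, the counts were 1561 averaged, 1466 in E9, 1751 in L5, and for L5 against E9 25 averaged, 26 in control and 48 in stress. Array weights gave 647 for L5 against E9 averaged over both conditions and 212 in control, and only the groups of the contrast gave 78 in control and 59 in stress; the cause was not tested. With an array left out, L5 against E9 ran from 278 (without E9 stress replicate 4) to 601 (without E9 stress replicate 3) averaged, from 76 to 141 in control, and from 90 to 646 in stress. The interaction count was 0 with 75th percentile scaling, with the strict filter on all arrays and with a replicate block, and with an array left out it ran from 0 to 23 (without E9 stress replicate 3; 2 without E9 stress replicate 1); the cause was not tested. The chromosome 9 share of line calls ran from 21.6% to 30.1% with an array left out and from 24.5% to 28.9% in the other alternatives run.

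With an estimated correlation the abscisic acid and iron lists had an adjusted p of 0.121 each for stress, and the abscisic acid list 0.345 for the interaction and 0.147 with fry. Over all their alternatives the stress values ran from 1.01e-05 to 0.121 for the abscisic acid list and from 7.14e-07 (by fry) to 0.121 for the iron list. With an array left out the abscisic acid list ran from 0.000463 to 0.127 for the interaction, and it lost its call without E9 control replicate 2, E9 stress replicates 2 and 4, L5 control replicate 3, and L5 stress replicates 3 and 4. For the line difference it ran from 0.0109 to 0.35, and passed without E9 stress replicates 1 and 3. Without its 2 loci in the chromosome 9 stretch the phosphate list had 0.123 for the line difference, the highest of 24 alternatives that began at 1.67e-05; these loci are its called members. By camera and fry the phosphate list kept its stress and interaction calls in all 24 alternatives (highest 0.0052 and 0.0483), but without Solyc03g005530 the exact permutation p of the interaction was 0.0894. The call was lost in 14 of 25 alternatives for Solyc09g059630, and in 15, 8 and 6 of 26 for Solyc05g052980, Solyc08g005610 and Solyc01g108280; it was gained in 7 of 26 for Solyc03g005530 and in 1 of 25 for Solyc04g078900. The uncalled Solyc08g062950 and Solyc12g096020 changed sign around 0 in some alternatives. Signal over background limits sizes for transcripts undetected in a group, and simulated interactions of 0.5 log2 were recovered in 19.4%.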

Other observations

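Transcripts that changed strongly under stress lay side by side more often than a random order gives. Of 311 transcripts called at 4-fold or more, 60 lay in 38 adjacent pairs that changed the same way, 25 pairs higher and 13 lower. The median of the random orders was 2 such pairs.

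The planned test compared the 38 pairs with 1000 random orders of the tested transcripts, of which the highest gave 10, so neighbours by chance are argued against. In 37 of the pairs both transcripts were called in both lines. Shared control of neighbouring genes is a candidate explanation for the 38 pairs, and so is hybridisation of similar sequences from duplicated neighbours to each other's probes, which was not tested.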
